A study of Homo sapiens with 18 samples.

How the data were processed

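Messenger RNA was selected on poly(T) beads, copied into cDNA with random primers and sequenced on a BGISEQ-500 instrument, per the labels. The 18 libraries fell into 6 groups of 3, for 2 cell lines and 3 agents at 20 nM with collection after 48 h. The series describes the 3 libraries of a group as biological replicates, and the labels do not say whether they were separate cultures or transfections. Every p-value of a single gene below therefore measures only the spread between these libraries. Fisher's exact tests below take genes as units, and the camera tests set the genes of a list against other genes. Genes are not independent replicates.

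The authors deposited a table of raw read counts per gene and library, whole numbers that were not normalized. They also deposited 4 tables of single comparisons with edgeR values, in which the authors give a log2 fold change, an average log2 CPM, a p-value with its false discovery rate, and a -log10 p. The 4 lists hold genes with an average log2 CPM of at least 5.00, a log2 fold change of at least 0.26 or at most -0.32, and no limit on the false discovery rate. The submitters' processing notes name BWA, edgeR and the builds GRCh37 and hg19, with no version or role. How reads were assigned to genes is not stated, nor whether the strand was used. Values of antisense genes, genes that overlap others, hosts of small nucleolar RNAs and close paralogs are therefore uncertain.

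The table of all genes had 13086 entries. The 2 entries without a gene name held 1.55% to 3.56% of a library's counts and were left out of the library sizes, and 16 gene names that a spreadsheet had turned into dates were restored through the Entrez ID. Of 13084 named genes, 12911 had counts in 293T, 11660 in the knockout line and 11487 in both. Another 1424 were entered as not available in the knockout line and 173 in 293T, which was not read as a count of 0. All 12911 genes listed for 293T had at least 1 read in control library 1, against 11755 to 11916 genes with a read in the other 8 libraries of that line. The 3 control columns without a line prefix were assigned to the knockout line, because the other 3 carry the prefix of 293T. The labels were followed in calling the second agent 124a, although the treatment text names another miRNA arm in its place. Of the counts repeated in the comparison tables, 8256 were checked against the table of all genes and 0 differed.

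Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which left 8456 genes. Library sizes were scaled by TMM, and all 18 libraries entered 1 quasi-likelihood fit with a mean per group, 12 residual degrees of freedom and robust estimation off. Tests were two-sided with Benjamini-Hochberg adjustment within each comparison, and the threshold was an adjusted p of 0.05. Errors, called standard errors in the captions, are the size of the log2 fold change divided by the square root of its F statistic in that fit. They approximate a standard error with 3 libraries per group and can be too small where a group has few reads. The comparisons were each agent with the MSA control in each line, the knockout line with 293T under the control, the difference of each agent's effect between the lines (knockout minus 293T), and 34a with 124a in each line. No block for the replicate number was fitted, since the labels give the number no meaning.

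Gene positions came from GENCODE release 44 lifted to GRCh37/hg19. Of the named genes 11564 matched by symbol and 1058 by Entrez ID, 462 did not match, and 10744 had an annotated 3′ UTR. By Entrez ID 13030 genes matched a RefSeq record. Seed sites were searched in those UTRs as CACTGCC and CACTGCCA for miR-34a-5p and as GTGCCTT and GTGCCTTA for miR-124-3p. Genes with a site were compared with genes that had a 3′ UTR and no 6mer site (ACTGCC or TGCCTT), with 50 shuffled seeds per miRNA beside them. Each agent's own sites were tested with camera as 7-base or longer and as 8-base sites, as planned, and only the adjustment over these 8 tests was chosen after the data were seen.

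Before the data were examined, 24 gene lists were written, and the tests, the alternatives and the rule for naming genes were fixed. The lists were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, with adjustment over the 19 lists that had at least 3 tested genes, and with the estimated correlation and fry beside it. They covered reported targets of miR-34a, miR-124, let-7 and the miR-17 family, genes repressed by PTBP1 or neuronal, the miRNA pathway, miRNA host genes, p53 targets, G1/S and DNA replication, and G2/M and mitosis. They also covered interferon and RNA sensing, the unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, Notch and Wnt, epithelial to mesenchymal and adhesion genes, cytosolic ribosomal proteins, replication-dependent histones, and immediate early and heat shock genes. Mitochondrially encoded genes and markers of fibroblasts, blood cells, endothelium and keratinocytes completed the set. Of these last 5 lists 0, 2, 1, 0 and 2 genes could be tested. Lists can share genes, such as NOTCH1 in the miR-34a and Notch lists and LAMC1 in the miR-124 and adhesion lists. Results of lists that share genes are not independent.

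Genes were named by that rule. It took DICER1 first, then the 8 highest and 8 lowest log2 fold changes past the threshold with at least 5 CPM in the higher group and no overlap between the 3 libraries of each group. It also took up to 4 members with the smallest adjusted p in each list described, and PTBP1, PTBP2, CDK6, CDK4, MET, SIRT1, JAG1, LDHA, HMGA2 and AGO2 whatever their result. For the differences between the lines it took the 5 highest and 5 lowest, and other genes named there were chosen after their values were seen. Of the genes that may be named this way, 1 is not reported here. PTBP1, PTBP2 and MET were not analysed here, and CDK6 had 1 to 6 reads per library and was not tested.

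The alternatives were RLE scaling, DESeq2 1.42.0, a robust spread, no filter, a filter at 5 CPM, a fit of only the groups compared, a replicate block, a fold limit of 1.2 or 0.8, other site types, and leaving out each library in turn. Removal of trends with GC content and transcript length, and leaving out the first 34a and first 124a library of 293T, were added after the data were seen. The fit was tested on simulated data, in which both lines took the spread of each gene from the fit of all 18 libraries. In 50 genes per size given a change of 1.5-fold, 64%, 54%, 56% and 48% were called for 34a in 293T, 124a in 293T, 34a in the knockout line and 124a in the knockout line. At 2-fold these shares were 72%, 74%, 78% and 78%. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.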

Results

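Messenger RNA was sequenced from 293T, a human embryonic kidney line that carries the SV40 large T antigen, and from a 293T line in which DICER1 had been knocked out. DICER1 encodes the ribonuclease that cuts miRNA precursors. Each line was transfected with 1 of 3 RNA agents, a control tRNA labelled MSA or 1 of 2 tRNA-based carriers labelled nCAR that hold miR-34a-5p or miR-124a-3p, named 34a and 124a below. There were 3 libraries per group and 18 in all. Total counts over named genes were 3266057, 3232104 and 3224207 in the 293T control, 3188126, 3225200 and 3250218 with 34a, and 3157318, 3223442 and 3200458 with 124a. In the knockout line they were 3244951, 3180252 and 3243671 in the control, 3219097, 3270981 and 3232301 with 34a, and 3281188, 3292656 and 3261091 with 124a. At this depth a count of 0 allows up to 3 reads, or 0.911 to 0.95 CPM, for counting error only. Between libraries of 1 group, chi-square per degree of freedom was 1.15 to 4.73, above sampling noise in every pair. The 2 cell lines separated on the first principal component, with 61.2% of the variance. The first 124a library of 293T lay at -22.5 on the third component (4.17%), against 5.72 and 3.99 for its replicates.

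DICER1 (chromosome 14 from 95552565 to 95624347 in GRCh37/hg19) had few reads. In 293T it had 9, 13 and 10 reads in the control, 8, 10 and 8 with 34a, and 9, 10 and 8 with 124a. In the knockout line it had 3, 2 and 4 reads in the control, 6, 4 and 3 with 34a, and 2, 4 and 4 with 124a. Its log2 fold change in the knockout line was -1.71 ± 0.41 (adjusted p = 0.0016), and it was not detectably different with either agent in either line (adjusted p from 0.75 to 0.96). The labels do not say which part of the gene was removed and the counts are not given by exon, so reads from the rest of the gene do not test the knockout.

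The first comparison asked which genes changed when 293T received 34a. Genes reported as miR-34a targets fell: GAS1, a membrane protein linked to growth arrest (-0.45 ± 0.08, adjusted p = 0.001, n = 3), the receptor NOTCH1 (-0.40 ± 0.09, 0.0046) and the cyclins CCNE2 (-0.37 ± 0.08, 0.0056) and CCND1 (-0.66 ± 0.20, 0.041). Targets of the tumour suppressor p53 rose, among them the stress-induced SESN2 (0.49 ± 0.06, adjusted p = 1.6e-05), the antiproliferative BTG2 (0.51 ± 0.08, 0.00033), the DNA damage gene DDB2 (0.68 ± 0.13, 0.001) and the nuclease AEN (0.24 ± 0.06, 0.0085). Genes of the unfolded protein and integrated stress response rose, with DDIT4, an inhibitor of mTORC1 (0.58 ± 0.06, adjusted p = 3.9e-07), the serine synthesis enzyme PHGDH (0.35 ± 0.05, 0.00012) and the cystine transporter SLC7A11 (0.51 ± 0.08, 0.00012). Over all 8456 genes tested, 250 rose and 268 fell, 34 of them at least 2-fold.

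Among the genes with the largest changes under 34a in 293T, CCDC170 rose by 1.68 ± 0.31 (adjusted p = 0.001), CRYL1 by 1.19 ± 0.20 (0.00031), CCDC152 by 1.18 ± 0.25 (0.0033) and ADM2, a peptide hormone, by 1.14 ± 0.14 (9.7e-06). LOC653160 (1.52 ± 0.32), LOC100506679 (1.26 ± 0.35), ANKRD24 (1.12 ± 0.28) and the antisense gene ACTA2-AS1 (1.52 ± 0.19, adjusted p = 1.2e-05) were also among the 8 highest. The lowest were LOC101927583 (-1.34 ± 0.25), USB1, an exonuclease that trims U6 RNA (-1.30 ± 0.24, adjusted p = 0.0011), LRRC4 (-1.26 ± 0.32), COMMD4 (-1.25 ± 0.32), NPB (-1.22 ± 0.35), SLC7A10 (-1.16 ± 0.30) and HEY1, a transcription factor induced by Notch (-1.14 ± 0.29, 0.017). SNORD44 (-1.30 ± 0.35), a small nucleolar RNA, is uncertain in a poly(A) library. In GRCh37/hg19, CCDC170 lies on chromosome 6 from 151815152 to 151942328, CRYL1 on chromosome 13 from 20977805 to 21100012, USB1 on chromosome 16 from 58033450 to 58055522 and HEY1 on chromosome 8 from 80674606 to 80680092. LDHA (1.25 ± 0.63, adjusted p = 0.27), AGO2 (0.33 ± 0.28, 0.58), JAG1 (0.26 ± 0.18, 0.49), HMGA2 (0.05 ± 0.08, 0.8), CDK4 (-0.09 ± 0.05, 0.32) and SIRT1 (-0.12 ± 0.18, 0.8) did not pass.

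Of 27 miR-34a targets tested with 34a in 293T, 0 rose and 4 fell over all genes, with the same 4 adjusted over the list alone (list adjusted p = 0.0021, and adjusted p = 0.0281 with an estimated correlation). Of 14 p53 targets, 5 rose and 0 fell, and 6 rose adjusted over the list alone (0.000106 and 0.027). Of 21 stress response genes, 4 rose and 0 fell, and 6 rose adjusted over the list alone (0.00449 and 0.0281). Heat shock genes were lower, with HSPA8 (-0.53 ± 0.08, adjusted p = 5.1e-05), BAG3 (-0.26 ± 0.06, 0.013) and DNAJA1 (-0.56 ± 0.16, 0.03) falling of 14 in the list with immediate early genes, and 5 adjusted over the list alone (list adjusted p = 0.0309, adjusted p = 0.172 with an estimated correlation). In the G1/S list 3 of 25 genes fell, FEN1 among them (-0.36 ± 0.07), and 5 fell and 1 rose adjusted over the list alone (0.0299, adjusted p = 0.172 with an estimated correlation). The let-7 targets had 1 of 15 lower, LIN28B (-0.24 ± 0.07, 0.038), and 2 adjusted over the list alone (0.0308, adjusted p = 0.205 with an estimated correlation). Ribosomal protein genes had 5 of 40 higher, RPL3 among them (0.47 ± 0.11), and 7 adjusted over the list alone (0.0309, adjusted p = 0.545 with an estimated correlation). The other 12 lists had adjusted p from 0.0501 to 0.909, and CDC20 (-0.38 ± 0.06), NRARP (-0.33 ± 0.07) and AGO4 (0.45 ± 0.09) passed singly. Without the first 34a and first 124a library, 564 genes passed, and the miR-34a, p53 and stress response lists had adjusted p = 0.0216, 0.000752 and 0.0151, or 0.0833, 0.0833 and 0.150 with an estimated correlation. The G1/S and mitosis lists passed there (0.0216 and 0.0283, or 0.208 and 0.243 with an estimated correlation). The heat shock, let-7 and ribosomal lists did not pass there (0.0621, 0.172 and 0.167). The count was 345, 288 and 313 without control library 1, control library 3 or 34a library 2, 341 with a fold limit of 1.2 or 0.8, and 901 with GC and length trends removed. Leaving out 1 library ended the call of AEN, ANKRD24, BAG3, CCND1, COMMD4, DNAJA1, HEY1, LIN28B, LOC100506679, LOC653160, LRRC4, NPB, RPL3, SLC7A10 or SNORD44.

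**Figure D1:**
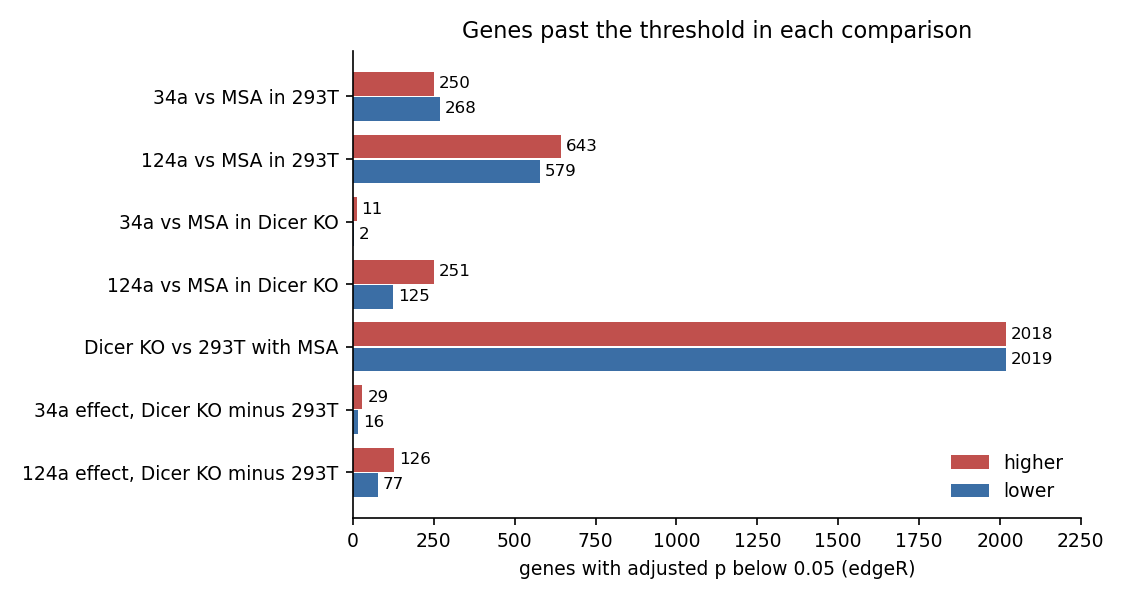
Bars show the number of genes with an adjusted p under 0.05 (horizontal axis, edgeR) that were higher or lower in each of 7 comparisons (vertical axis). The counts ran from 2 lower genes with 34a in the knockout line to 2019 lower genes between the lines.

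The same question was asked of 124a in 293T. Reported miR-124 targets fell, with VAMP3, a vesicle SNARE (-1.21 ± 0.07, adjusted p = 5.2e-13, n = 3), the galactosyltransferase B4GALT1 (-0.79 ± 0.06, 3.2e-10), SNAI2, a repressor of epithelial genes (-0.85 ± 0.07, 7e-10), and the scaffold protein IQGAP1 (-0.76 ± 0.07, 2.8e-09). The p53 targets SESN2 (0.64 ± 0.06, 1.6e-08), BTG2 (0.81 ± 0.08, 1.9e-08), AEN (0.51 ± 0.06, 7.3e-08) and the kinase PLK3 (1.03 ± 0.19, 0.00036) rose. Reads of replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, rose, with HIST1H2BK (0.69 ± 0.11, 2.1e-05), HIST3H2A (0.75 ± 0.13, 0.00014), HIST2H2BE (1.2 ± 0.28, 0.0029) and HIST1H1C (0.64 ± 0.17, 0.008). In the same libraries the 2 entries without a gene name held 2.98% ± 0.51 of all counts, against 1.90% ± 0.12 in the control (SD, n = 3). A link between these entries and the histone reads was not tested. The heat shock genes HSPA8 (-0.50 ± 0.08, 1.8e-05) and BAG3 (-0.40 ± 0.06, 4e-05) and the transcription factor JUN (-0.32 ± 0.06, 0.00012) fell, while IER2 rose (0.28 ± 0.08, 0.018). In all, 643 genes rose and 579 fell, 124 of them at least 2-fold.

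The largest rises under 124a in 293T were those of DINO, a noncoding RNA next to CDKN1A (2.58 ± 0.33, adjusted p = 1.6e-06), TXLNB (2.29 ± 0.35, 2.5e-05), the adhesion molecule NECTIN4 (2.26 ± 0.28, 9.9e-07), the sodium channel SCN9A (2.08 ± 0.23, 1.2e-07), ACTA2-AS1 (1.86 ± 0.18, 1.2e-08), MYOM2 of the sarcomere (1.84 ± 0.11, 4.4e-13), SYT11 (1.68 ± 0.22, 2.2e-06) and the cadherin FAT3 (1.68 ± 0.15, 1.3e-09). The lowest were NOP56, a ribosome assembly gene that hosts small nucleolar RNAs (-2.01 ± 0.32, 3.2e-05), SNORD44 (-1.80 ± 0.38), LOC101927583 (-1.71 ± 0.27), LOC101930452 (-1.55 ± 0.41), PLK5 (-1.49 ± 0.31), LOC100288162 (-1.44 ± 0.36), VAMP3 and STPG3-AS1 (-1.17 ± 0.25). In GRCh37/hg19, DINO lies on chromosome 6 from 36645386 to 36646336, NECTIN4 on chromosome 1 from 161040788 to 161059348, SCN9A on chromosome 2 from 167051695 to 167232511, NOP56 on chromosome 20 from 2633239 to 2639039 and VAMP3 on chromosome 1 from 7831356 to 7841492. CDK4, the kinase partner of cyclin D, fell (-0.32 ± 0.05, adjusted p = 3.9e-05). LDHA (1.16 ± 0.64, 0.25), AGO2 (0.48 ± 0.27, 0.27), HMGA2 (0.11 ± 0.08, 0.44), JAG1 (-0.04 ± 0.19, 0.92) and SIRT1 (-0.05 ± 0.18, 0.9) did not pass.

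Of 22 miR-124 targets tested with 124a in 293T, 0 rose and 13 fell, with 13 adjusted over the list alone (list adjusted p = 3.01e-16, and 1.34e-05 with an estimated correlation), and their median was -0.38. Of 14 p53 targets 6 rose and 0 fell, with 8 and 1 adjusted over the list alone (3.56e-06 and 0.00587). Of 9 histone genes 6 rose, with 7 adjusted over the list alone (2.75e-05 and 0.00717). Of 14 immediate early and heat shock genes 1 rose and 5 fell, with 1 and 8 adjusted over the list alone (0.000387 and 0.0265). The G1/S list had 2 higher and 4 lower of 25, FEN1 (-0.46 ± 0.07) and CDC6 (-0.30 ± 0.08) among the lower, with 2 and 6 adjusted over the list alone (0.0395, adjusted p = 0.152 with an estimated correlation). The miR-34a targets under this agent had 0 higher and 4 lower of 27, CCNE2 (-0.38 ± 0.08) among them, and the list did not pass (0.265, with a median of -0.03 and a mean of 0.01). The adhesion list did not pass (0.197, with a median of 0.05 and a mean of -0.03), although 1 member rose and 5 fell, with COL4A1 (-0.68 ± 0.08), VIM (-0.50 ± 0.05) and LAMC1 (-0.34 ± 0.05) falling. The remaining 12 lists had adjusted p from 0.0637 to 0.857. Without the first 34a and first 124a library 1281 genes passed, and the miR-124, p53, histone and heat shock lists had adjusted p = 1.10e-14, 2.81e-06, 5.18e-05 and 0.00271. The glycolysis and Notch lists passed there too, both upward (0.0114 each, and 0.0355 each with an estimated correlation). So did the G1/S, mitosis and let-7 lists, all downward (0.0114, 0.0114 and 0.036, or 0.117, 0.182 and 0.207 with an estimated correlation). Leaving out 1 library ended the call of CDC6, HIST1H1C, IER2 or LOC101930452.

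Seed sites asked whether genes that carry a match to the agent's miRNA in the 3′ UTR moved as a class. For 124a in 293T, 30.7% of genes that fell carried a 7-base or longer site, against 16.3% of other genes (odds ratio 2.28, 95% interval 1.86 to 2.78, Fisher's exact test adjusted over 20 tests, p = 9.4e-14). For 124a in the knockout line these shares were 43% and 16.9% (odds ratio 3.71, 2.49 to 5.48, adjusted p = 9.41e-10). For 34a in 293T they were 24.6% and 18.0% (odds ratio 1.48, 1.09 to 2.00, adjusted p = 0.0347). Among genes that rose with 34a in 293T the share was 22.6% against 18.1% (odds ratio 1.32, 0.932 to 1.84, adjusted p = 0.208), an interval that overlaps the former. Between the lines under the control, 34a sites were more frequent among genes lower and higher in the knockout line (odds ratios 1.19 and 1.18, adjusted p = 0.042 each), and 124a sites among the higher (1.26, adjusted p = 0.00394). Over all tested genes the shifts were small. The 1238 genes with a 124a site differed from the 3538 without one by a median of -0.03 in 293T (camera adjusted over 8 tests, adjusted p = 0.131), or by -0.06 with UTR length matched, past the threshold before adjustment, and by 0.00 in the knockout line (0.503). Genes with an 8-base 124a site differed by -0.07 (adjusted p = 0.00016) and -0.02 (0.112) with 124a in these lines. Those with an 8-base 34a site differed by -0.05 (adjusted p = 0.123) and 0.03 (0.112) with 34a. The 1306 genes with a 34a site differed from 4687 without one by -0.02 in 293T (adjusted p = 0.541), or by -0.0030 with UTR length matched, and by 0.03 in the knockout line (0.112). Shuffled seeds were set beside another value, the shift of genes with a 7-base match against all genes without that match. It was -0.04 and -0.00099 for 124a in 293T and the knockout line and -0.02 and 0.03 for 34a. Of 50 shuffled seeds, 0, 3, 2 and 21 gave as low a shift. Sites of 34a were also more frequent among genes that rose with 124a, with 25% against 17.7% in 293T (adjusted p = 0.000169) and 27.9% against 17.9% in the knockout line (adjusted p = 0.000937). None of the shares given here was matched on UTR length. With 124a, genes with a 34a site differed by 0.02 in 293T (camera, unadjusted p = 0.404), or 0.0014 with UTR length matched (0.671). In the knockout line they differed by 0.036 (camera, unadjusted p = 0.0588), or 0.038 with UTR length matched (0.0674).

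In the knockout line the question was which genes responded to 34a there. Adhesion and extracellular matrix genes rose, with TGFB1, a growth factor of matrix production (0.34 ± 0.06, adjusted p = 0.011, n = 3), and the laminin LAMA1 (0.33 ± 0.07, 0.035), beside LAMB1 (0.25 ± 0.06, 0.11) and COL4A2 (0.24 ± 0.06, 0.15). Of 18 genes in that list 2 rose over all genes and 7 adjusted over the list alone (list adjusted p = 1.86e-06, and 0.00169 with an estimated correlation). The RNA-binding protein MSI1 (0.56 ± 0.08, 0.00032), the elongation factor EEF1A2 (0.54 ± 0.07, 0.00016) and the adhesion molecule ICAM5 (0.66 ± 0.12, 0.011) rose, as did COL14A1 (0.49 ± 0.10, 0.015), BCL9L (0.47 ± 0.09, 0.011), ARID3A (0.45 ± 0.09, 0.013) and AMOT (0.38 ± 0.07, 0.013). ID3, an inhibitor of differentiation (-0.37 ± 0.08, 0.035), and NCOA5 (-0.31 ± 0.06, 0.034) fell. Altogether 11 genes rose and 2 fell, with 742 at an unadjusted p under 0.05. With GC and length trends removed 19 rose and 19 fell, and the adhesion list was not tested again in that fit. Log2 fold changes here correlated with GC content and transcript length across 8109 genes, which are not independent replicates (Spearman rho 0.117 and 0.114). In GRCh37/hg19, MSI1 lies on chromosome 12 from 120779133 to 120806967, EEF1A2 on chromosome 20 from 62119366 to 62130592, TGFB1 on chromosome 19 from 41807492 to 41859827 and ID3 on chromosome 1 from 23884417 to 23885992.

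Of the 27 miR-34a targets, edgeR called 0 in either direction with 34a in the knockout line, and the list did not pass (adjusted p = 0.159, median 0.04). GAS1 was at 0.04 ± 0.08 (adjusted p = 0.95), NOTCH1 at 0.15 ± 0.09 (0.62), NOTCH2 at 0.14 ± 0.06 (0.44), CCNE2 at -0.08 ± 0.08 (0.82), CCND1 at 0.67 ± 0.24 (0.35) and DLL1 at 0.40 ± 0.15 (0.38). The Notch and Wnt list had 0 of 23 past the threshold and 1 higher adjusted over the list alone (0.00918, adjusted p = 0.0685 with an estimated correlation), with NOTCH3 at 0.41 ± 0.11 (0.14) and WNT5A at 0.40 ± 0.19 (0.54). The G1/S and G2/M lists had 0 of 25 and 0 of 17 called, with list adjusted p = 0.0399 each and adjusted p = 0.234 and 0.326 with an estimated correlation. The p53 list did not pass (0.425), nor did the other 13 lists (0.0555 to 0.714). AGO2 (0.53 ± 0.22, 0.46), JAG1 (0.31 ± 0.22, 0.72), HMGA2 (0.12 ± 0.10, 0.79), SIRT1 (0.02 ± 0.21, 0.99), CDK4 (-0.02 ± 0.05, 0.96) and LDHA (-0.30 ± 0.39, 0.87) did not pass. Each of the 6 libraries mattered: the count was 5, 3 and 5 without control library 1, 2 or 3 and 7, 4 and 4 without 34a library 1, 2 or 3, and 38 with GC and length trends removed. Only MSI1 and EEF1A2 of the 11 named genes past the threshold stayed there in all 6 of these fits.

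With 124a in the knockout line, miR-124 targets fell: VAMP3 (-0.58 ± 0.07, adjusted p = 1.4e-06, n = 3), B4GALT1 (-0.39 ± 0.06, 0.00016), SNAI2 (-0.46 ± 0.08, 0.0002) and the collagen-modifying enzyme PLOD3 (-0.37 ± 0.07, 0.00046). The p53 targets BTG2 (0.46 ± 0.06, 1.4e-05), the quinone oxidoreductase TP53I3 (1.53 ± 0.33, 0.0048), DDB2 (0.50 ± 0.12, 0.013) and SESN2 (0.25 ± 0.07, 0.02) rose. The Notch genes NOTCH1 (0.55 ± 0.08, 0.0001), NOTCH3 (0.65 ± 0.10, 0.00018) and NRARP (0.39 ± 0.07, 0.001) rose, as did TGFB1 (0.59 ± 0.06, 2.3e-07), COL4A2 (0.41 ± 0.06, 9.1e-05) and the neurofilament gene NEFL (0.63 ± 0.05, 2.8e-09). Of the mitosis genes ASPM fell (-0.38 ± 0.09, 0.014), with UBE2C at -0.91 ± 0.29 (0.065), CDC20 at -0.18 ± 0.06 (0.068) and CCNB2 at -0.24 ± 0.07 (0.058). Over all genes 251 rose and 125 fell, 20 of them at least 2-fold. A fit of only the groups compared called 523 genes here and 816 with 124a in 293T, against 376 and 1222 in the fit of all libraries.

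The highest under 124a in the knockout line were NECTIN4 (2.71 ± 0.28, adjusted p = 1.3e-07), PPL, a desmosomal plakin (2.19 ± 0.34, 0.00012), TP53I3, ACTA2-AS1 (1.26 ± 0.13, 8.6e-08), TPBGL (1.26 ± 0.25), CCDC120 (1.13 ± 0.30), CCDC184 (1.13 ± 0.23) and C10orf10 (1.10 ± 0.25). The lowest were C1orf159 (-1.0 ± 0.26), NOP56 (-0.92 ± 0.25), the proton pump genes ATP6V0B (-0.86 ± 0.25) and ATP6V0E1 (-0.66 ± 0.08, 1.2e-06), SMCO4 (-0.80 ± 0.22), IFRD2 (-0.69 ± 0.07, 2.6e-08), HOTAIRM1 (-0.69 ± 0.17) and FAM162A (-0.67 ± 0.09, 1.4e-05). In GRCh37/hg19, PPL lies on chromosome 16 from 4932508 to 5010742, TP53I3 on chromosome 2 from 24300303 to 24308731, IFRD2 on chromosome 3 from 50325163 to 50330349 and ATP6V0E1 on chromosome 5 from 172410774 to 172462448. CDK4 fell (-0.22 ± 0.05, 0.011), while HMGA2 (0.25 ± 0.10, 0.18), JAG1 (0.39 ± 0.22, 0.36), AGO2 (0.36 ± 0.22, 0.42), SIRT1 (0.13 ± 0.21, 0.82), DLL1 (0.44 ± 0.15, 0.093) and LDHA (-0.62 ± 0.41, 0.47) did not pass.

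Of 22 miR-124 targets in the knockout line with 124a, 1 rose and 8 fell, with 2 and 10 adjusted over the list alone (list adjusted p = 3.46e-05, and 0.00585 with an estimated correlation). Their median was -0.10. Of 14 p53 targets 4 rose, with 7 adjusted over the list alone (1.16e-05 and 0.00721). Of 17 mitosis genes 1 fell, with 10 adjusted over the list alone (2.6e-07 and 0.0278). Of 23 Notch and Wnt genes 3 rose, with 4 adjusted over the list alone (0.00259 and 0.0278), and of 18 adhesion genes 5 rose and 2 fell, VIM among the lower (-0.30 ± 0.05), with 6 and 2 adjusted over the list alone (0.018 and 0.0379). The stress response list had 1 higher and 2 lower of 21, SLC7A11 (-0.35 ± 0.09) and SLC7A5 (-0.24 ± 0.06), with 1 and 3 adjusted over the list alone (0.0216, adjusted p = 0.0531 with an estimated correlation). The neuronal list had 1 higher of 4, NEFL, with 2 adjusted over the list alone (0.0216, adjusted p = 0.0531 with an estimated correlation). The other 12 lists had adjusted p from 0.167 to 0.897. Log2 fold changes in this comparison correlated with GC content across 8109 genes, which are not independent replicates (Spearman rho 0.226), and with that trend and the one with length removed 46.7% of calls were higher, against 66.8%. Of the lists only the p53 targets were tested again here with those trends removed. The count was 232 and 247 without control library 1 or 3, and 206 and 221 without 124a library 1 or 2. Leaving out 1 library ended the call of ASPM, ATP6V0B, C1orf159, CCDC120, CDK4, DDB2, HOTAIRM1, NOP56, SESN2, SLC7A11, SMCO4 or TP53I3.

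**Figure D2:**
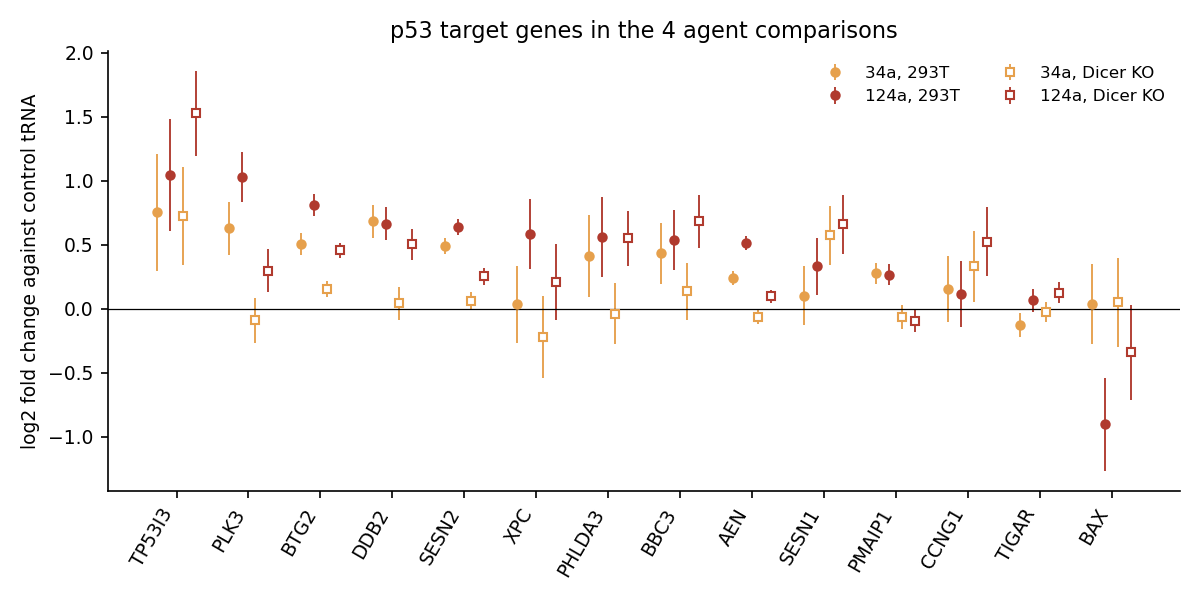
Points show log2 fold changes against control tRNA (vertical axis) of the 14 p53 targets (horizontal axis) for 34a and 124a in both lines, with bars of 1 standard error and 3 libraries per group. SESN2 was at 0.49 with 34a and 0.64 with 124a in 293T, and at 0.06 and 0.25 in the knockout line.

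The knockout line was set against 293T under the control to ask how the lines differed before either miRNA was added. IFIH1, the sensor of long double-stranded RNA, rose 23.6-fold (log2 4.56 ± 0.25, adjusted p = 1.3e-15, n = 3), from 5, 6 and 3 reads to 125, 97 and 98, and the endosomal RNA sensor TLR3 rose by 2.63 ± 0.32 (5.5e-08). Reported targets of the miR-17 family rose, with the autophagy adaptor FYCO1 (1.80 ± 0.06, 9.5e-21), ZNFX1 (1.36 ± 0.07, 8.8e-16), the channel PKD2 (0.91 ± 0.07, 1e-11) and the phosphatase PTPN4 (0.86 ± 0.08, 5.7e-10). Of 23 Notch and Wnt genes 11 fell and 3 rose (list adjusted p = 0.0395, and 0.121 with an estimated correlation), the lower ones with NOTCH3 (-2.62 ± 0.09, 1.2e-20), NRARP (-0.89 ± 0.07, 6.5e-12), AXIN2 (-1.06 ± 0.13, 1.1e-07) and TCF7L1 (-0.68 ± 0.09, 4.5e-07). In all, 2018 genes rose and 2019 fell, 1024 of them at least 2-fold.

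The other large rises in the knockout line were those of FAAH2, an amide hydrolase (4.4 ± 0.40, adjusted p = 1.1e-10), the collagen COL12A1 (4.22 ± 0.27, 5.8e-14), ZNF804A (3.70 ± 0.17, 1.2e-17), IGFN1 (3.50 ± 0.56), CLSTN2 (2.85 ± 0.25), C2CD4A (2.75 ± 0.41) and the phosphatase DUSP2 (2.73 ± 0.12, 1.6e-17). The lowest were STUM (-5.69 ± 0.32, 2.5e-15), the hormone STC1 (-5.12 ± 0.68, 2.3e-07), the transcription factor FOXB1 (-4.26 ± 0.27, 3.7e-14), FAM84B (-4.20 ± 0.10, 5.8e-25), the growth factor BMP2 (-4.15 ± 0.25, 1.3e-14), UTF1 (-3.75 ± 0.52), ELFN1 (-3.71 ± 0.53) and PNMA2 (-3.60 ± 0.18, 8.9e-17). STC1 rested on 50 reads in 293T and 1 in the knockout line, a ratio of 0.0201 (95% exact counting interval 0.000499 to 0.117). That interval is wider than the error of 0.68 given for STC1 implies. STUM had 126, 104 and 119 reads in 293T and 5, 0 and 1 in the knockout line. In GRCh37/hg19, IFIH1 lies on chromosome 2 from 163123584 to 163175194, COL12A1 on chromosome 6 from 75794042 to 75915983, STUM on chromosome 1 from 226736465 to 226796931, FAM84B on chromosome 8 from 127564688 to 127570723 and BMP2 on chromosome 20 from 6748333 to 6760893. HMGA2, a chromatin protein and let-7 target, fell (-1.40 ± 0.09, 1.5e-13), as did JAG1 (-0.52 ± 0.21, 0.04), while AGO2 rose (0.77 ± 0.26, 0.017) and LDHA rose from few reads (2.26 ± 0.53, 0.00081). SIRT1 (-0.45 ± 0.20, 0.065) and CDK4 (-0.10 ± 0.05, 0.1) did not pass. Leaving out 1 library ended the call of AGO2, COL1A1 or JAG1.

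Of 14 miR-17 family targets 10 rose and 1 fell in the knockout line, with the same counts adjusted over the list alone and a median of 0.70 (list adjusted p = 0.00104, and 0.0346 with an estimated correlation). Of 11 interferon and RNA sensing genes 6 rose and 1 fell, IRF9 (0.88 ± 0.16) and IFI44L (2.31 ± 0.43) among the higher, with the same counts adjusted over the list alone (0.0395, adjusted p = 0.121 with an estimated correlation). The counts of the Notch and Wnt list were also the same adjusted over the list alone. The interferon list held 36 genes, 16 of them among the named genes, and genes not available in 1 line or with few reads were not tested. The antiviral OAS3, at 31.8 reads per 293T library, was not available in the knockout line. Interferon genes that were low there may thus be missing from these counts. Of 15 let-7 targets 5 rose and 2 fell, PLAGL2 (0.72 ± 0.06) among the higher and HMGA2 and IGF2BP3 (-0.46 ± 0.07) the lower, and the list did not pass (0.523). The miR-34a and miR-124 lists had 6 higher and 6 lower of 27 and 7 higher and 7 lower of 22, CCND2 among the higher of the latter (0.94 ± 0.07), with adjusted p = 0.878 each. For the miR-34a list the median was -0.13 and the mean 0.05. Of the 12 miRNA pathway genes tested AGO2 rose and DICER1, SND1 (-0.21 ± 0.05) and AGO4 (-0.42 ± 0.10) fell (0.771). The other 12 lists had adjusted p from 0.115 to 0.968. Markers of other cell types were few and went both ways: the fibroblast collagens COL3A1 (-3.01 ± 0.61, 0.00013) and COL1A1 (-0.28 ± 0.09, 0.012) fell, the globin HBA1 rose (2.20 ± 0.62, 0.0042), and the epithelial SFN (0.58 ± 0.38, 0.21) and EPCAM (0.58 ± 0.38, 0.22) did not pass.

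**Figure D3:**
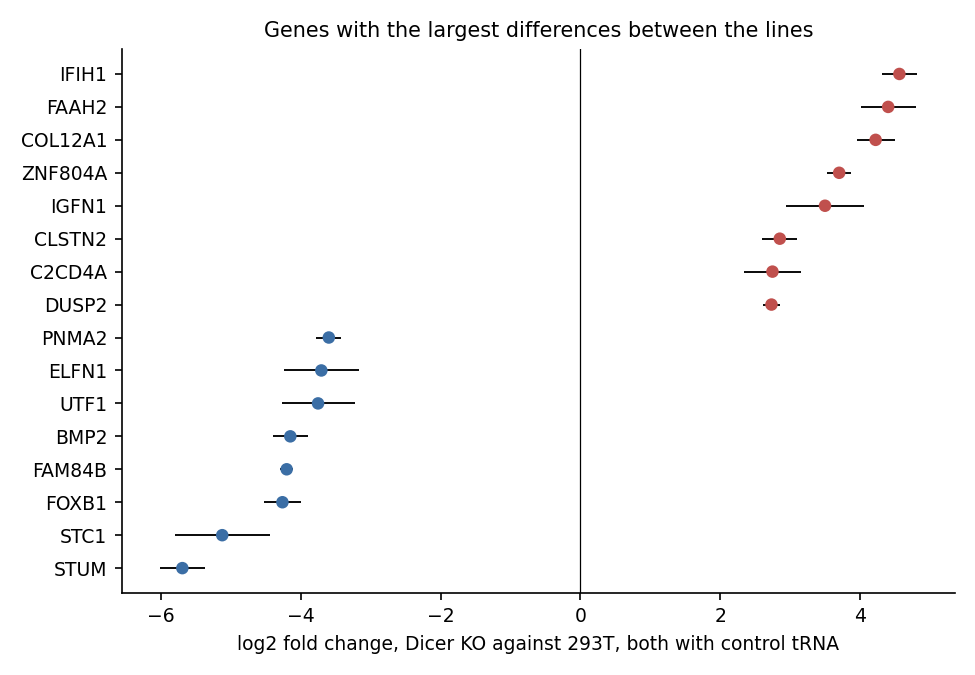
Points show log2 fold changes of the knockout line against 293T under control tRNA (horizontal axis) for the 8 highest and 8 lowest genes named (vertical axis), with bars of 1 standard error and 3 libraries per group. They ran from -5.69 for STUM to 4.56 for IFIH1.

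Whether 34a acted differently in the 2 lines was tested as the difference of its effects, knockout minus 293T. The miR-34a targets had higher changes in the knockout line, with a difference of 0.55 ± 0.12 for NOTCH1 (adjusted p = 0.025, n = 3) and 1.33 ± 0.31 for CCND1 (0.038), beside GAS1 (0.48 ± 0.12, 0.054) and DLL1 (0.67 ± 0.20, 0.12). The changes of SESN2 (-0.43 ± 0.09, 0.022), DDIT4 (-0.41 ± 0.09, 0.023) and PHGDH (-0.33 ± 0.08, 0.037) were lower there, as was that of MIR34AHG, the host transcript of miR-34a (-0.79 ± 0.16, 0.017). In total 45 genes differed, 29 with a higher and 16 with a lower change in the knockout line, and 1002 at an unadjusted p under 0.05. The other highest differences were those of HSPA1L (1.95 ± 0.46, 0.038), a paralog of other HSP70 genes, USB1 (1.53 ± 0.33, 0.022), the insulin signalling adaptor IRS1 (0.94 ± 0.19, 0.019) and ICAM5 (0.94 ± 0.16, 0.0043), and the other lowest those of CTSO (-1.49 ± 0.32, 0.022), ACTA2-AS1 (-1.26 ± 0.25, 0.015), ZC3H6 (-1.01 ± 0.21, 0.02) and PMM1 (-0.65 ± 0.13, 0.017). Of 27 miR-34a targets 2 differed, both upward, and 7 adjusted over the list alone (list adjusted p = 0.000267, and 0.0215 with an estimated correlation). The count was 24 and 13 without 293T control library 1 or 3, 16 without 34a library 2 of 293T, 27 and 11 without knockout control library 1 or 3, 24 and 13 without 34a library 1 or 2 of the knockout line, 71 without the first 34a and first 124a library of 293T, and 202 with GC and length trends removed, 52.5% of them higher, against 64.4%. Of the 18 named genes past the threshold ICAM5 alone stayed there in every fit with 1 library left out.

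For 124a the same test found 203 genes, 126 with a higher and 77 with a lower change in the knockout line, or 155 and 153 with GC and length trends removed. Reported miR-124 targets had higher changes there, by 0.64 ± 0.10 for VAMP3 (adjusted p = 0.00057, n = 3), 0.53 ± 0.10 for IQGAP1 (0.0024), 0.40 ± 0.09 for the magnesium transporter MAGT1 (0.0072) and 0.37 ± 0.07 for the laminin LAMC1 (0.0028). Of 22 targets 9 differed, all upward, and 12 adjusted over the list alone, with a median of 0.38 (list adjusted p = 1.18e-11, and 7.85e-05 with an estimated correlation). SLC7A11 (-0.88 ± 0.12, 4.7e-05), MIR34AHG (-0.80 ± 0.15, 0.0027) and AEN (-0.42 ± 0.08, 0.0027) had lower changes there. COL4A1 (0.77 ± 0.12, 0.00066) and JUN (0.41 ± 0.08, 0.0027) had higher ones, at 0.09 ± 0.09 (0.66) and 0.10 ± 0.05 (0.38) with 124a in the knockout line. The highest differences were those of RELL2 (1.48 ± 0.41), C10orf10 (1.32 ± 0.36), LBH (1.29 ± 0.31), SMPD3 (1.26 ± 0.34) and CD81-AS1 (1.12 ± 0.26, 0.016), and the lowest those of LOC101929066 (-3.04 ± 0.83), HIST1H2AC (-2.26 ± 0.63), PRRT3 (-1.89 ± 0.50), WEE2-AS1 (-1.79 ± 0.37, 0.0055) and HAT1 (-1.62 ± 0.45). The count was 132 and 113 without 293T control library 1 or 3, 122 and 129 without knockout control library 1 or 3, 105 and 100 without 124a library 1 or 2 of the knockout line, and 308 in all with GC and length trends removed. Leaving out 1 library ended the call of C10orf10, CD81-AS1, HAT1, HIST1H2AC, HSPA8, LBH, LOC101929066, MYC, NRARP, PRRT3, RELL2, SESN2, SMPD3 or SNAI2, and another alternative also ended that of all of these but CD81-AS1, LBH and SESN2.

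**Figure D4:**
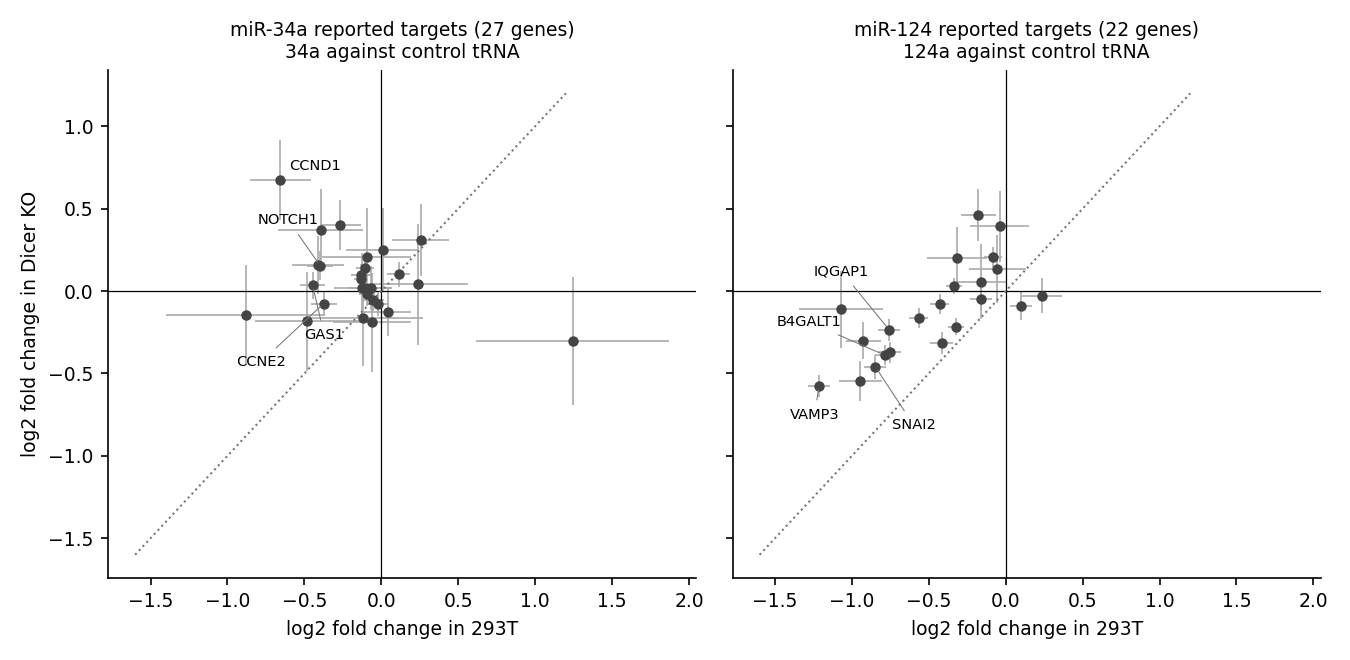
Points show log2 fold changes of 27 miR-34a targets with 34a and 22 miR-124 targets with 124a, in 293T (horizontal axis) and the knockout line (vertical axis), with bars of 1 standard error, 3 libraries per group and a dotted line where both effects are equal. VAMP3 was at -1.21 in 293T and -0.58 in the knockout line, and NOTCH1 at -0.40 and 0.15.

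Set against each other, 34a and 124a differed in 412 genes in 293T (173 higher and 239 lower with 34a) and in 92 in the knockout line (39 and 53). The miR-124 targets were higher with 34a in both, 13 of 22 in 293T, with 14 adjusted over the list alone (list adjusted p = 1.03e-24), and 6 of 22 in the knockout line, with 12 higher and 1 lower adjusted over the list alone (2.03e-13), at 1.3e-06 and 3.74e-05 with an estimated correlation. Of 14 p53 targets 2 were lower with 34a in 293T (0.0279, adjusted p = 0.113 with an estimated correlation) and 1 in the knockout line, with 8 adjusted over the list alone (1.07e-06 and 0.00413). Histone genes were lower with 34a in 3 of 9 in 293T, with 6 adjusted over the list alone (0.000469 and 0.0207), and in 1 of 9 in the knockout line, with 2 adjusted over the list alone (0.0015 and 0.0384). Stress response genes were higher with 34a in 4 of 21 in 293T, with 7 adjusted over the list alone (0.000469 and 0.012), and in 1 in the knockout line, with 2 higher and 1 lower adjusted over the list alone (0.0149 and 0.0495). The miR-34a targets had 1 higher and 2 lower of 27 in 293T, and the list did not pass in either line (0.111 and 0.943). The count in 293T was 221, and in the knockout line 278, in a fit of only the groups compared. In the knockout line it was 48 and 45 without 34a library 1 or 3, 52, 46 and 55 without 124a library 1, 2 or 3, and 186 with GC and length trends removed.

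Both agents called many of the same genes in 293T. Of the genes past the threshold, 328 were shared in the same direction, 155 higher and 173 lower, and 6 in opposite directions. Independence would give 19 higher and 18.4 lower. Across genes, which are not independent replicates, the fold changes of both agents correlated at 0.611 with a covariance of 0.0616, against 0.496 and 0.0243 in 50 simulated sets of unchanged groups that share the controls. The control libraries cannot be split between the agents, so part of the excess may come from sharing them. In the knockout line 12 genes were shared, 10 higher and 2 lower, against 0.327 and 0.0296 under independence. The fold changes there had a correlation of 0.567 against 0.503 and a covariance of 0.0465 against 0.0309. The simulated sets of both lines took the spread of each gene from all libraries (common biological coefficient of variation 0.0533). That coefficient was 0.0633 within 293T and 0.0418 within the knockout line. The simulated covariance may thus be too low for 293T and too high for the knockout line. The shared count in 293T was 217 and 183 without control library 1 or 3, 211 without 34a library 2, and 573 with GC and length trends removed. That of the knockout line was 4, 3 and 4 without control library 1, 2 or 3, 6, 3 and 3 without 34a library 1, 2 or 3, 7 without either of 124a libraries 1 and 2, and 29 with GC and length trends removed.

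Between the lines, whose controls are separate, 117 genes rose with 124a in both and 65 fell in both (odds ratios 12.7 and 16.5, Fisher's exact test, adjusted p = 2.34e-65 and 8.07e-43), with 10 in opposite directions. With 34a, 4 rose and 2 fell in both (adjusted p = 0.000279 and 0.001). Genes that rose or fell with 124a in 293T had medians of 0.18 and -0.11 in the knockout line, against 0.46 and -0.38 in 293T. For 34a these medians were 0.05 and -0.06 against 0.40 and -0.31. Across all tested genes, which are not independent replicates, fold changes correlated between the lines at r = 0.306 for 124a and 0.0973 for 34a. The shared count for 34a was 1 or 2 with any 1 of the 6 knockout libraries of this comparison left out, and rose with GC and length trends removed. For 124a it was 121 without 124a library 2 of the knockout line and 282 with GC and length trends removed.

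The authors' deposited tables list 655 genes for 124a in 293T (382 higher and 273 lower, 492 with a false discovery rate under 0.05), 360 for 34a in 293T (248 and 112, 261), 276 for 124a in the knockout line (208 and 68, 225) and 85 for 34a in the knockout line (79 and 6, 25). Over all genes the authors' deposited values have 919, 581, 603 and 51 genes with a false discovery rate under 0.05 in these comparisons. Of the genes tested in both, 899 of 1222 genes called for 124a in 293T, 494 of 518 for 34a in 293T, 373 of 376 for 124a in the knockout line and 13 of 13 for 34a in the knockout line were also under 0.05 in the authors' deposited values, and 0 were called in opposite directions. The log2 fold changes of the authors' deposited tables and of the fit correlated at 1.00 across genes in all 4.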

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

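Of the tests in this part, the differences between the lines were planned, and the tests of totals, spread, equal response, kept shares, shared controls, the unnamed entries and other splits of the libraries were chosen after the result was seen, as were the GC and length correction and the leaving out of the first 34a and first 124a library together. Leaving out single libraries was planned.

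The effect of 34a differed between the lines in 45 genes, by the test of the difference of its effects (knockout minus 293T). Genes with a higher change in the knockout line included HSPA1L (1.95), USB1 (1.53), CCND1 (1.33), IRS1 (0.94), ICAM5 (0.94), NOTCH1 (0.55), the chaperones HSPA8 (0.47) and BAG3 (0.38), and the Notch inhibitor NRARP (0.43). Genes with a lower change were CTSO (-1.49), ACTA2-AS1 (-1.26), ZC3H6 (-1.01), MIR34AHG (-0.79), PMM1 (-0.65), SESN2 (-0.43), DDIT4 (-0.41), the amino acid transporter SLC7A5 (-0.35) and PHGDH (-0.33). Lists with a higher change were the miR-34a targets (adjusted p = 0.000267, and 0.0215 with an estimated correlation), let-7 targets (0.00892 and 0.117), Notch and Wnt genes (0.0246 and 0.0742), adhesion genes (0.0249 and 0.0585) and immediate early and heat shock genes (0.00087 and 0.0334). Lists with a lower change were the p53 targets (0.00087 and 0.028), the stress response (0.00206 and 0.028), ribosomal proteins (0.00168 and 0.319) and histones (0.00584 and 0.053). Of these the let-7, adhesion, ribosomal and histone lists had 0 members called by edgeR over all genes, with 0, 2, 0 and 0 adjusted over the list alone and 1002 genes of all kinds at an unadjusted p under 0.05. The miR-34a and Notch lists share NOTCH1, so they are not separate results. None of the lists was tested again for this difference with GC and length trends removed. Without the first 34a and first 124a library of 293T the let-7 and adhesion lists did not pass (0.133 and 0.0563), and with an estimated correlation the p53 and stress response lists did not (0.0627 and 0.0783). Without knockout control library 3 the count was 11, and without 293T control library 3 or 34a library 2 of the knockout line it was 13 each.

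The effect of 124a differed between the lines in 203 genes by the same test. Among miR-124 targets the change was higher in the knockout line for VAMP3 (0.64), IQGAP1 (0.53), MAGT1 (0.40), SNAI2 (0.39) and LAMC1 (0.37). It was also higher for RELL2 (1.48), C10orf10 (1.32), LBH (1.29), SMPD3 (1.26), CD81-AS1 (1.12), COL4A1 (0.77), FEN1 (0.47), BAG3 (0.46), JUN (0.41), the chaperones HSPA5 (0.39) and HSPA8 (0.38), NRARP (0.35) and MYC (0.25). It was lower for LOC101929066 (-3.04), HIST1H2AC (-2.26), PRRT3 (-1.89), WEE2-AS1 (-1.79), HAT1 (-1.62), SLC7A11 (-0.88), MIR34AHG (-0.80), DDIT4 (-0.47), SLC7A5 (-0.44), AEN (-0.42) and SESN2 (-0.38). Lists with a higher change were the miR-124 targets (adjusted p = 1.18e-11), immediate early and heat shock genes (1.54e-06), adhesion genes (8.38e-06), let-7 targets (0.0394) and miR-34a targets (0.0415), with 7.85e-05, 0.00488, 0.00199, 0.266 and 0.118 with an estimated correlation. The miR-124 and adhesion lists share LAMC1, so they are not separate results. Lists with a lower change were histones (0.000785), p53 targets (0.0364) and mitosis genes (0.0409), with 0.0192, 0.118 and 0.34 with an estimated correlation. These differences correlated with GC content across 8109 genes, which are not independent replicates (Spearman rho 0.217). Only the miR-124 list was tested again for this difference with GC and length trends removed. Without those first libraries the mitosis list did not pass (0.198), and the glycolysis list passed with a lower change (0.0234, and 0.0652 with an estimated correlation). Without 124a library 2 of the knockout line the count was 100, without 124a library 1 it was 105, and without 293T control library 3 it was 113.

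The 2 entries without a gene name held 2.81% ± 0.41 of all counts with 34a in 293T and 2.98% ± 0.51 with 124a (SD, n = 3), above each of the 3 control libraries (1.90% ± 0.12). The exact two-sided permutation test gave p = 0.1 in each, the smallest that 3 against 3 can give, and an adjusted p of 0.2 over 4 tests. They carry RefSeq numbers of the kind given to noncoding RNA, and which genes these are was not analysed here.

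Far fewer genes passed the threshold with 34a in the knockout line (13) than in 293T (518). Read totals were equal, with a ratio of 1.00, and the spread between knockout libraries was lower (biological coefficient of variation 0.0418 against 0.0633), so neither accounts for it. An equal response that missed the threshold is argued against too. The genes called in 293T had a median of 0.059 in the knockout line in the direction of 293T (95% bootstrap interval 0.045 to 0.070), against 0.35 in 293T. That interval resamples genes, which are not independent replicates, and leaves out the spread between libraries. The 293T median is raised by choosing the genes on the same libraries. With genes called without 1 control and 1 34a library, the libraries left out gave medians of 0.26, 0.33 and 0.35, against 0.079, 0.051 and 0.060 in the knockout line. A part for Dicer in the response to 34a stays open. The miR-34a targets differed between the lines (camera adjusted p = 0.000267), as would be seen if the carrier had to be cut by Dicer. Less agent or any weaker response would give the same, and the p53, stress response and heat shock lists differed too. The miR-34a list also differed for 124a (camera adjusted p = 0.0415), though not with an estimated correlation. Targets of 124a, on a carrier with the same label, still fell in the knockout line with 124a (camera adjusted p = 3.46e-05). How much 34a entered the knockout cells and how much Dicer was left were not measured and stay open, as does any other difference between these 2 lines.

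The miR-124 targets fell less in the knockout line than in 293T, with medians of -0.10 and -0.38. The median of their differences, taken gene by gene, was 0.38. With trends in GC content and transcript length removed it was 0.39, which argues against those trends as the cause. No action of 124a in the knockout line is argued against as well, since these targets still fell there (adjusted p = 3.46e-05). Less 124a in the knockout cells stays open. Genes called higher without a site kept 37.3% of their 293T change (95% interval 30.7 to 44.3) and the reported targets called lower 39.8% (28.8 to 50). Genes called lower kept 30.6% (24.4 to 36.7) with a site and 22.0% (16.9 to 26.9) without one, and genes called higher with a site 46.1% (37.6 to 55.6). The intervals resample genes, which are not independent replicates, and leave out the spread between libraries. All these groups of genes were chosen on the 293T libraries that the shares are measured against. GC and length trends were not removed, and how changes scale with the amount of agent was not measured. Less agent and a weaker action on targets therefore cannot be told apart. Whether any Dicer was left was not measured, so an action without Dicer stays open.

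The p53 targets rose with 124a in both lines and with 34a in 293T. Without the first 34a and first 124a library of 293T the lower of the 2 medians in 293T was 0.23, and with GC and length trends removed the lowest of the 3 medians was 0.34, so neither those libraries nor those trends account for it as a whole. The list call for 34a in 293T was then lost with an estimated correlation (adjusted p = 0.0833), its median moving from 0.34 to 0.23. The shared 293T controls are argued against for 124a, since the list also rose in the knockout line with its own controls (adjusted p = 1.16e-05). An effect of the agents on p53, in a line whose T antigen binds p53, was not tested and stays open.

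Other splits of the libraries were counted. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison only the real split, 1 of 10, gave as many genes. The real counts and the highest of the other splits were 518 and 0 for 34a in 293T, 1222 and 9 for 124a in 293T, 13 and 0 for 34a in the knockout line, 376 and 0 for 124a in the knockout line, 4037 and 0 between the lines, and 412 and 43, and 92 and 0, for 34a against 124a in 293T and the knockout line. For the difference of the 34a effects, 4 of 100 splits gave 45 genes or more and the highest other gave 115. For the difference of the 124a effects, 5 of 100 gave 203 or more and the highest other gave 526. The splits with more genes than the real one each exchanged 4 of the 6 knockout libraries between agent and control and left 293T in place. That leaves a smaller effect of opposite sign in the knockout line beside the full effect in 293T, so these counts reflect the structure of the libraries. The shares of 4 and 5 in 100 therefore decide nothing on chance.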

How the results depend on the processing

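Removal of GC and length trends and the leaving out of the first 34a and first 124a library of 293T were chosen after the data were seen, and the other alternatives were planned. RLE scaling, DESeq2, a robust spread, both filters and the replicate block kept all counts of genes within 1.5 times the reported ones; with the replicate block the counts were 479, 1210, 11, 342 and 4020 for the 5 main comparisons. Same-number libraries of 1 line had low correlations (-0.18 to 0.20), and libraries of different number were not set beside them. Whether the numbers pair the libraries is thus not settled, and the paired fit was only an alternative. No gene called in the report changed sign under any alternative, but calls were lost. With all libraries or without both first ones, at least 1 alternative ended the call of CCND1 and NPB with 34a in 293T, of CDC6, HIST1H1C, IER2, LOC101930452, MIR503HG and RPL13 with 124a in 293T, of LAMA1 and NCOA5 with 34a and ATP6V0B, CCDC120, DDB2, SESN2 and SMCO4 with 124a in the knockout line, and of AGO2 and JAG1 between the lines. For the differences it ended those of CCND1, HSPA1L and NRARP with 34a and C10orf10, HAT1, HIST1H2AC, HSPA8, LOC101929066, MYC, NRARP, PRRT3, RELL2, SMPD3 and SNAI2 with 124a. That left 37 of 39, 45 of 51, 9 of 11, 30 of 35, 67 of 69, 15 of 18 and 18 of 29 named calls in these 7 comparisons. Under RLE scaling and DESeq2 the median of all genes ran from -0.02 to 0.01. At this depth and with 3 libraries per group, simulated 1.2-fold changes were called in 4% to 24% of genes, and DESeq2 gave no adjusted p for 6681 genes with 34a in 293T.

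A fit of only the groups compared gave 221 genes for 34a against 124a in 293T, down from 412. In the knockout line it gave 278, up from 92. Fewer genes were tested (7820 and 7554) and fewer libraries set the spread in both lines, which alone does not account for opposite moves. The spread over all libraries (biological coefficient of variation 0.0533) lay below that of 293T (0.0633) and above that of the knockout line (0.0418). The count with 124a moved likewise, to 816 in 293T and 523 in the knockout line, and that with 34a little, to 528 and 15. The larger moves run as a spread set within each line would give, which was not tested apart. The fold limit gave 341 genes for 34a in 293T by its construction. Removal of GC and length trends gave 901 genes for 34a in 293T, 38 for 34a in the knockout line, 202 and 308 for the differences between the lines, 186 for 34a against 124a in the knockout line, and shared counts of 573 and 29 between agents and 18 and 282 between lines, and without the first 34a and first 124a library of 293T the 34a effects differed in 71 genes; the cause was not tested. With the trends removed the share of higher calls was 46.7% for 124a and 50% for 34a in the knockout line, against 66.8% and 84.6%. With an estimated correlation 3, 1, 1, 4 and 4 lists passed for 34a in 293T, 34a in the knockout line, the lines, and the 34a and 124a differences, and fry, which does not compare a list with other genes, passed 14 lists for 124a in 293T and 13 between the lines.

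For seed sites the shift of 124a in 293T was -0.073 with 8-base sites, -0.060 with UTR length matched and -0.035 in genes of at least 5 CPM, all past the threshold before adjustment, but 0.012 with any 6-base site, and that of 34a in 293T was -0.0030 with UTR length matched. In the knockout line the shift of 124a was -0.022 with 8-base sites and -0.0071 with UTR length matched, against 0.00. The former was past the threshold before adjustment but not after it (camera adjusted p = 0.112). For 34a there it was 0.029 in genes of at least 5 CPM, past the threshold before adjustment. The cause was not tested.

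Signs reversed in genes that were not called. Without 293T control library 3, HMGA2 was at -0.031 with 34a, and SIRT1 at 0.01 and JAG1 at 0.22 with 124a. With 124a in 293T, SIRT1 was at 0.055 and HMGA2 at -0.047 without 124a library 1, JAG1 at 0.03 without 124a library 3, and SIRT1 at 0.067 and HMGA2 at -0.034 without both first libraries. With 34a in the knockout line, CDK4 was at 0.0095 and SIRT1 at -0.13 without control library 2, LDHA at 0.054 without control library 3, SIRT1 at -0.13 without 34a library 2, and GAS1 at -0.016 with GC and length trends removed. With 124a there, DICER1 was at -0.10 and SIRT1 at -0.013 without control library 2, and DICER1 at -0.037 without 124a library 2 and at -0.042 without 124a library 3. Over all libraries left out in turn HMGA2 ran from -0.031 to 0.13 with 34a in 293T. With 124a in 293T SIRT1 ran from -0.13 to 0.055, JAG1 from -0.17 to 0.22 and HMGA2 from -0.047 to 0.18. With 34a in the knockout line CDK4 ran from -0.046 to 0.0095, SIRT1 from -0.13 to 0.19 and LDHA from -0.64 to 0.054, and with 124a DICER1 ran from -0.097 to 0.36 and SIRT1 from -0.013 to 0.30. The seed shift of 124a there, 0.00 in the report, was -0.027 without control library 2, past the threshold before adjustment, and -0.016 without 124a library 3.

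With 1 library left out the counts ran from 288 to 349 for 34a in 293T, 869 to 1234 for 124a in 293T, 3 to 7 for 34a and 206 to 277 for 124a in the knockout line, and 3623 to 3736 between the lines. They ran from 11 to 56 and 100 to 234 for the 34a and 124a differences, and 277 to 376 and 45 to 64 for 34a against 124a in 293T and the knockout line. Shared counts ran from 183 to 392 and 3 to 10 between agents in 293T and the knockout line, and 1 to 5 and 121 to 252 between lines for 34a and 124a. Seed shifts ran from -0.026 to -0.0087 for 34a and -0.036 to -0.0072 for 124a in 293T, and from 0.013 to 0.039 and -0.027 to 0.023 in the knockout line. Fewer libraries lower the power by construction, which does not account for counts above the reported ones. Without 124a library 1 of 293T, 1234 genes passed with 124a in 293T, against 1222, and 392 were shared between agents there, against 328. The differences reached 56 without 293T control library 2, against 45, and 234 without 124a library 2 of 293T, against 203. No other cause was tested.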

Other observations

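All tests of values by library and by transcript number in this part were chosen after the data were seen, while the gene lists were written before.

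Of 8 tested transcripts that host miRNAs, 1 rose and 2 fell with each agent in 293T. MIR34AHG, the host of miR-34a and a p53 target, rose by 0.67 ± 0.11 with 34a (adjusted p = 0.00016, n = 3) and 1.05 ± 0.10 with 124a (8.4e-09). MIR17HG, the host of the miR-17 family, changed by -0.44 ± 0.09 (0.0024) and -0.62 ± 0.09 (1.2e-05), and MIR503HG by -0.80 ± 0.22 (0.028) and -0.77 ± 0.22 (0.016), a call that ended for both agents when 1 library was left out. As a list of 8 tested genes the hosts did not pass with either agent (adjusted p = 0.807 and 0.857) or between the lines (0.219), where MIR210HG (-3.07 ± 0.35, 1.6e-08) and MIR503HG (-1.30 ± 0.25, 5.7e-05) fell. With 124a in 293T other single genes passed in lists that did not, such as the glycolytic ENO2 (0.89 ± 0.11, 1.7e-06), the RNA sensor DDX58 (0.94 ± 0.22, 0.0028), NEFL (0.49 ± 0.06, 6.7e-07), NOTCH3 (0.39 ± 0.07, 0.00011) and the let-7 target NRAS (-0.57 ± 0.08, 3.7e-06). DDIT4 (0.49 ± 0.06) and SLC7A11 (0.53 ± 0.08) rose and the chaperone HSPA5 fell (-0.45 ± 0.06, 8.2e-06), in a stress response list with 5 higher and 4 lower of 21 (adjusted p = 0.857). The cholesterol list did not pass (adjusted p = 0.0637), and RPL3 rose (0.36 ± 0.11) and RPL13 fell (-0.44 ± 0.13) in the ribosomal list (0.81), calls that ended when 1 library was left out. NRAS also fell with 124a in the knockout line (-0.44 ± 0.08, 0.00058).

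Between the lines many lists held large changes in both directions. Of 21 stress response genes 10 rose and 5 fell, with the transporter SLC7A5 (2.44 ± 0.06, adjusted p = 1.6e-24) and the chaperones DNAJB9 (1.81 ± 0.13) and CALR (0.75 ± 0.05) higher and DDIT4 lower (-1.64 ± 0.06, 3.2e-19), and the list did not pass (0.115). Of 12 cholesterol synthesis genes 6 rose and 3 fell, with 8 and 3 adjusted over the list alone (0.189), MSMO1 (1.67 ± 0.18) among the higher and PMVK (-1.11 ± 0.19) among the lower. Of 18 glycolysis and hypoxia genes 4 rose and 4 fell (0.968), the glucose transporter SLC2A3 (2.32 ± 0.12) and ADM (1.59 ± 0.12) higher and BNIP3 (-1.04 ± 0.08) and PGK1 (-0.33 ± 0.05) lower. The 4 neuronal genes tested split, the neurofilaments NEFL (1.55 ± 0.06, 1.9e-19) and NEFM (0.70 ± 0.13) higher and SYP (-1.10 ± 0.12) and RBFOX3 (-2.02 ± 0.26) lower (0.878). Of 14 p53 targets 5 rose and 2 fell (0.115), with BTG2 (2.40 ± 0.07, 2.4e-21), AEN (1.00 ± 0.06) and TIGAR (0.82 ± 0.09) higher and PMAIP1 lower (-0.45 ± 0.09). Of 9 histone genes 5 rose (0.115), HIST1H2BK (0.95 ± 0.10) and HIST1H1C (0.89 ± 0.16) among them. The adhesion list had 6 higher and 8 lower of 18 (0.878), with ESRP2 (0.89 ± 0.07), TGFB1 (0.69 ± 0.07) and VIM (0.50 ± 0.05) higher and COL4A1 lower (-1.11 ± 0.08), and the heat shock list 7 higher and 3 lower of 14 (0.516), with HSPA8 at 0.93 ± 0.07 and HSPB1 at -0.86 ± 0.10. Mitosis genes had 7 higher and 1 lower of 17 (0.147), G1/S genes 6 and 6 of 25 (0.878), and ribosomal proteins 10 and 4 of 40 (0.771), with RPS20 at -2.20 ± 0.40.

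The sign of the median, the mean and the test differed in several lists that did not pass. These were the miRNA pathway, host and Notch lists for 34a in 293T, the miR-34a, adhesion and ribosomal lists for 124a in 293T, the neuronal, miR-17 and stress response lists for 34a in the knockout line, and the G1/S list for 124a there. Between the lines they were the miR-34a, neuronal, G1/S, glycolysis and adhesion lists. For the differences of effects they were the neuronal, miR-17, G1/S and cholesterol lists with 34a and the stress response and ribosomal lists with 124a. For 34a against 124a they were the let-7 and host lists in 293T and the miR-34a, let-7, miRNA pathway, host, cholesterol, glycolysis and adhesion lists in the knockout line.

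Counts were lower in genes with more annotated transcripts. The median of the mean count per library was 29.4 reads in 4361 genes with 1 RefSeq transcript, 26.4 in 1660 genes with 2, 13.3 in 2074 genes with 5 to 8 and 9.33 in 2878 genes with 9 or more (Spearman rho -0.151 across 13018 genes, which are not independent replicates). GAPDH averaged 8.44 reads and LDHA 6.78, against 20424.5 for ACTB and 3015.89 for EEF1A1. Changes of genes such as LDHA, DICER1 and CDK6 therefore rest on few reads, and how reads that match several transcripts were counted is not stated.

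Of the 1424 genes entered as not available in the knockout line, 13 averaged at least 10 reads per 293T library. The highest were the homeobox gene UNCX (49.1 reads) and the antiviral OAS3 (31.8 reads), and no value is given for them in the knockout line.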
